A study of Danio rerio with 16 samples.

How the data were processed

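Whole zebrafish embryos were profiled 24 hours after fertilisation (24 hpf) on 16 single-colour Agilent arrays, 4 for each of 4 groups. Per the labels, each sample was total RNA from about 50 embryos, and replicates 1 to 4 of every group came from 4 independent experiments. The embryos had been injected at the 1 to 4 cell stage and kept at 28 degrees in water with PTU, which blocks pigment, and the RNA was labelled with Cy3. The groups were control, p53 morpholino, Sbds morpholino, and both morpholinos together. The control label says that a morpholino was injected without naming a target, while the scanner files of those arrays are called mock, so what the control embryos received is not known beyond that. Both named morpholinos are labelled ATG, that is, directed at the start codon.

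The deposited scanner files hold 1 array each, with spot signals as intensity on a linear scale, per the file headers and column names. Their headers name Feature Extraction 10.7.3.1 and the protocol GE1_107_Sep09, which subtracted local background, removed spatial and multiplicative trends within each array, and did no scaling between arrays. The authors also deposited a table of processed values, which their own processing notes tie to limma without a version. The values of that deposited table are on a log2 scale centred near 0 for each probe, as read from the numbers: they correlated with the probe-centred log2 scanner signal with r from 0.753 to 0.971 per array over 22422 spots, in the same direction. How that table was centred and normalised between arrays is not stated, and it was used only as an alternative.

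The scanner signal was converted to log2, and each array's 75th percentile over non-control probes was subtracted, so that a level of 0 equals that percentile. Spots of the same probe were averaged. Of 43603 probes, the 28324 that the scanner software called well above background on all 4 arrays of at least 1 group were tested. Probes were named through the gene tables supplied for this organism: 25258 by accession, 2766 by symbol, 1675 by synonym, 1454 by another accession and 321 by the name in the file, and 12129 had no name. In all, 28634 probes carried a real symbol, for 14570 genes. Positions are those of the danRer6 grid in the scanner files and were not mapped again, since no genome was at hand.

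Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 16 arrays, with 12 residual degrees of freedom, and tests were two-sided. Changed probes had a Benjamini-Hochberg adjusted p under 0.05 over the tested probes. The comparisons were Sbds morpholino against control, both morpholinos against p53 morpholino, p53 morpholino against control, both against Sbds morpholino, both against control, and the interaction, which is the second comparison minus the first. In all, 22 gene lists were tested with camera (preset correlation 0.01) on 12503 genes, each represented by its brightest tested probe, after 169 missing values were filled with the group mean. List p values were adjusted over the 22 lists within a comparison, and camera with an estimated correlation and fry were run beside it. The p53 target and apoptosis lists share 4 genes.

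The groups, comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule always names sbds, cdkn1a, mdm2, ptf1a, pdx1 and ins, and a further gene that is not reported here. It then takes genes with a real symbol, an adjusted p under 0.05, signal well above background on all arrays compared and the same sign between all 4 same-numbered arrays. From these come the 10 largest rises and 10 largest falls for the first and second comparison, and 5 and 5 for the others. It adds up to 4 members of each list with the smallest adjusted p, the 2 genes with the smallest adjusted p among those above background in only 1 of the compared groups, and, where nothing passed, the 5 smallest p. For these 2 genes the dim arrays were raised to the lowest signal called above background on the same array, and the fold is given as at least. This bounds the estimate and leaves out its sampling error. Other list members are named in places after their values were seen.

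Each slide carried 1 array of every group and 1 replicate number, and was scanned on its own, so replicate number, slide and scan cannot be told apart. The position of an array on its slide was the same for all arrays of a group, so position and group cannot be told apart either. Whether the numbers pair the samples was checked by correlating arrays after subtracting each group's mean from every probe. All 24 pairs of arrays from different groups with the same number had r above 0.1 (0.224 to 0.842, median 0.715), and 24 of the 72 pairs with different numbers did (-0.753 to 0.75, median -0.593). The different-number pairs above 0.1 all joined slide 1 with slide 2 or slide 3 with slide 4. The check therefore shows a difference between these pairs of slides more clearly than pairing by number. Each number is also 1 slide, so a fit with replicate number as a block, which has 9 residual degrees of freedom, was run too. It is given beside the counts of changed probes and beside some of the genes and lists whose call it changes. List counts are without the block unless stated, and some are larger with it. The correlation within a replicate number estimated for the block as a random effect was 0.613.

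The 75th percentile of the array signal ran from 80.3 to 344 intensity units, and 55.0% to 76.5% of probes were well above background. No spot was saturated. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.25 for Sbds morpholino against control. Tested on simulated data with 100 probes changed at each fold, limma recovered 24% of changes of 2-fold and 81% of changes of 4-fold, with 3 calls among unchanged probes. Far fewer probes changed there than in the real Sbds comparison, so these shares do not carry over to it directly. The blocked fit recovered 70% and 93%, with 31 calls among unchanged probes.

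The alternatives were quantile normalization, centring on the median of tested probes, normexp background correction with an offset of 50, no filter or a filter on all 16 arrays, replicate number as a fixed or a random block, only the groups compared, eBayes with trend and robust, a fold minimum of 1 on the log2 scale, the deposited table, the mean of all probes of a gene, and leaving out each array in turn. Tables were handled with data.table (1.17.8), Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. No array was left out of the results reported. Fits without single arrays did not use the block, so slide differences stayed in their residual. A call that ended in them was not tested without that array under the block.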

Results

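Transcript levels were measured in whole zebrafish embryos at 24 hpf after injection of morpholinos, antisense oligomers that block a chosen RNA. Sbds takes part in the maturation of the large ribosomal subunit, and p53 is the transcription factor that responds to ribosomal and DNA stress. The 16 arrays fell into 4 groups of 4: control embryos, embryos given the p53 morpholino (p53 morphants), embryos given the Sbds morpholino (Sbds morphants) and embryos given both (double morphants). The title of the study asks whether ribosome biogenesis genes act in pancreas development without p53. The 4 groups separate the effect of the Sbds morpholino (the Sbds effect) without the p53 morpholino from that with it. The p53 protein was not measured, so how far the p53 morpholino reduced it is not known. Levels are log2 signal relative to each array's 75th percentile, and changes are log2 fold changes ± SE from limma with n = 4 arrays per group. The 75th percentile ran from 80.3 to 344 intensity units, lower on slides 1 and 2 (80.3 to 192) than on slides 3 and 4 (235 to 344). Each slide held 1 array of every group, so differences within a slide are given beside the main results as the lowest and highest of 4 slides.

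The Sbds morpholino's target could be followed only in part. The sbds probe A_15_P162876 (danRer6 chromosome 15, 2334535 to 2334594) was well above background on 2 of 4 control arrays, 2 of 4 p53 morphant arrays, 3 of 4 Sbds morphant arrays and 2 of 4 double morphant arrays, so sbds was not tested. Its mean level was -4.33 ± 2.49 (SD, n = 4) in control embryos and -4.14 ± 2.09 in Sbds morphants. Morpholinos at a start codon block translation, so a transcript level does not measure how far a protein was reduced. The labels name the same Sbds morpholino for all Sbds and double morphants. Effects of this oligomer apart from Sbds therefore cannot be told apart from those of Sbds loss. No probe could be named for cdkn1a, which was not analysed here.

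The comparison of Sbds morphants with control embryos asks what the Sbds morpholino does without the p53 morpholino. There 12 of 23 p53 target genes rose, and 10 of 30 neural and 16 of 36 cell cycle genes fell. The falls as lists were not past the test with an estimated correlation (adjusted p = 0.137 and 0.103). The gene for mdm2, the ubiquitin ligase that degrades p53 (chromosome 4, 22929850 to 22929908), rose 5.12-fold (2.36 ± 0.29, adjusted p = 0.000222, 2.25 to 2.64 within slides), and by 2.47 ± 0.14 in its second probe (adjusted p = 2.46e-07). The largest fall was in plp1a, which encodes a membrane proteolipid of the nervous system (chromosome 14, 15912870 to 15912929): -3.47 ± 0.51, adjusted p = 0.000805, -4.14 to -3.13 within slides. In total 2348 probes changed, 991 higher and 1357 lower, standing for 543 named genes higher and 774 lower.

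Of the 23 measured p53 target genes, 12 rose, none fell and 11 did not pass the test, and 12 rose adjusted over the list alone. The list's median was 0.96 (camera adjusted p = 2.85e-11, or adjusted p = 0.000706 with an estimated correlation, 0.67 to 1.23 within slides), and 0.49 without replicate 2 of the controls and 0.55 with normexp background. Members with small p were bbc3 (2.87 ± 0.20, adjusted p = 9.41e-07), which encodes the cell death protein Puma, the stress gene gadd45aa (3.34 ± 0.27, adjusted p = 4.66e-06) and the initiator caspase casp8 (3.07 ± 0.27, adjusted p = 9.08e-06). Among 27 measured apoptosis genes, 6 rose and none fell (6 higher and 1 lower adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.000805, adjusted p = 0.0135 with an estimated correlation, 0.13 to 0.33 within slides), and 0.31 with quantile normalization, 0.29 with a filter on all 16 arrays and 0.30 with the mean of all probes of a gene. They included baxa (1.39 ± 0.28, adjusted p = 0.00684) and mcl1b (0.75 ± 0.16, adjusted p = 0.00994), which act for and against cell death. bbc3, casp8 and baxa stand in both lists. The executioner caspase gene casp3a did not pass the test, at -0.35 (adjusted p = 0.831).

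**Figure D1:**
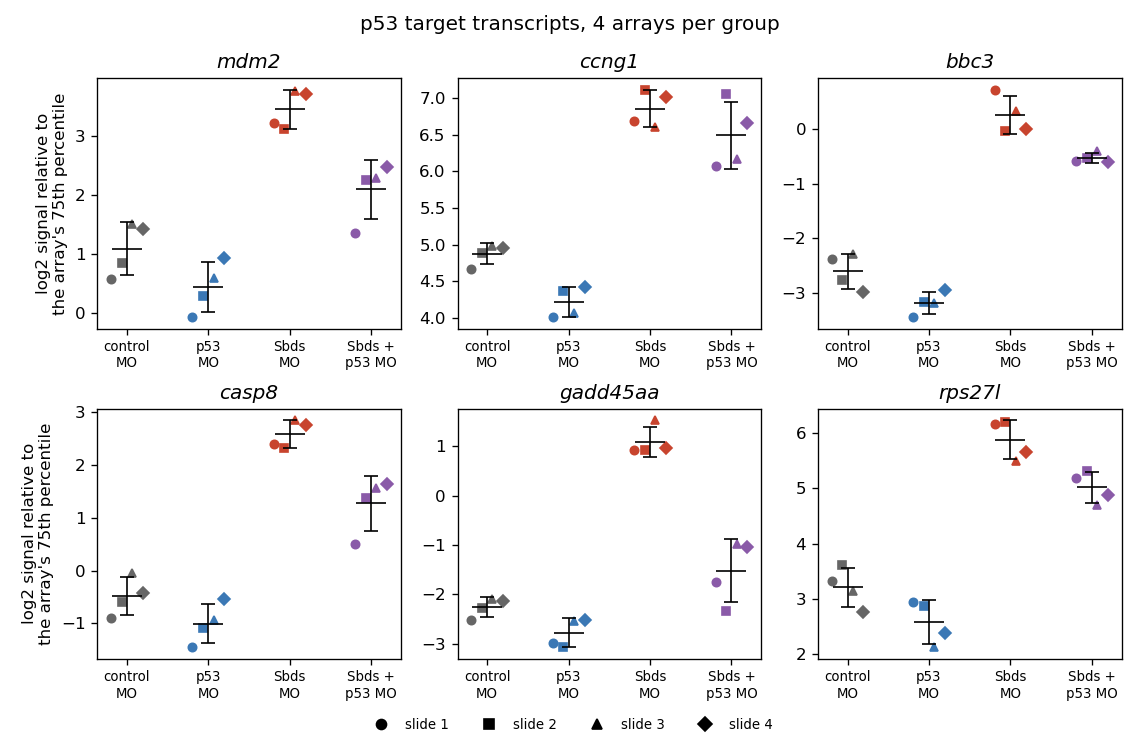
Level of 6 p53 target genes on each of the 16 arrays, as log2 signal relative to the array's 75th percentile (y axis) by group (x axis). Points are arrays with a symbol per slide, horizontal lines are group means and bars are SD (n = 4). mdm2 had a mean of 1.09 in control embryos, 0.44 in p53 morphants, 3.45 in Sbds morphants and 2.09 in double morphants.

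Of 30 measured neural genes, 10 fell in Sbds morphants, none rose and 20 did not pass, and 12 fell adjusted over the list alone. The list's median was -0.70 (camera adjusted p = 8.25e-07, adjusted p = 0.137 with an estimated correlation, -0.69 to -0.40 within slides). The Notch ligand gene dlb fell by 1.25 (SE 0.14, adjusted p = 9.62e-05) and the neuronal splicing factor gene nova2 fell by 1.12 (adjusted p = 0.000276). The neurogenic factor gene neurod4 fell by 1.68 (adjusted p = 0.000617) and the radial glia gene gfap fell by 1.68 (adjusted p = 0.000632). Among the 10 named genes with the largest falls, beside plp1a, were her4.4, a Notch target (-2.59 ± 0.40, adjusted p = 0.00121), and genes for the neural transcription factors helt (-2.56 ± 0.35), otpb (-2.53 ± 0.36), scrt1a (-2.29 ± 0.32), foxn4 (-2.29 ± 0.37) and otpa (-2.21 ± 0.44). The other falls among these 10 were comtd1, slc22a6l and leg1.2, at -2.57, -2.19 and -2.19.

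**Figure D2:**
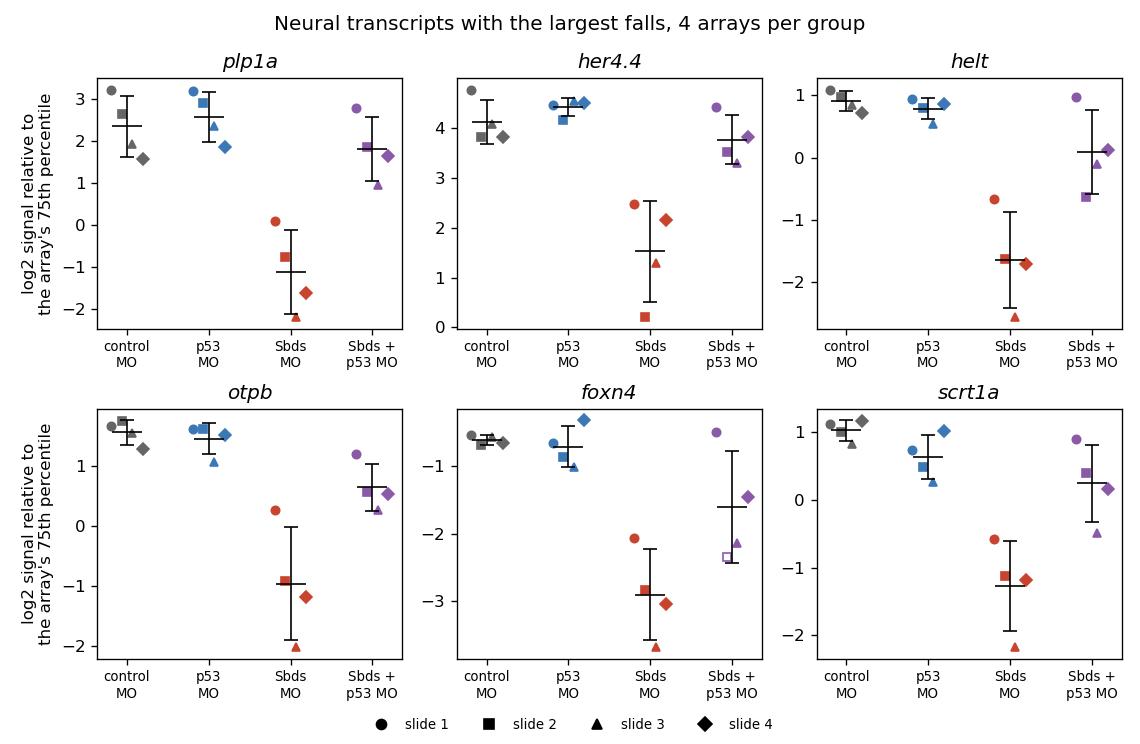
Level of 6 genes of the nervous system on each of the 16 arrays, as log2 signal relative to the array's 75th percentile (y axis) by group (x axis). Points are arrays with a symbol per slide (open where the probe was not well above background), horizontal lines are group means and bars are SD (n = 4). plp1a had a mean of 2.35 in control embryos, 2.58 in p53 morphants, -1.12 in Sbds morphants and 1.81 in double morphants.

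Of 36 measured cell cycle genes, 16 fell and none rose (20 fell adjusted over the list alone), with a median of -0.67 (camera adjusted p = 2.99e-15, adjusted p = 0.103 with an estimated correlation, -0.88 to -0.54 within slides). The members with the smallest p act in or control DNA replication: the helicase subunits mcm3 (-1.37 ± 0.16, adjusted p = 0.000114), mcm6 (2.46-fold lower, adjusted p = 0.000114) and mcm7 (2.14-fold lower, adjusted p = 0.000258), and gmnn, the gene for geminin (-1.22 ± 0.15, adjusted p = 0.000183).

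Genes that build ribosomes and genes that encode ribosomal proteins had medians of opposite sign. Of 90 measured ribosome biogenesis genes, 5 rose and none fell (2 rose adjusted over the list alone), with a median of 0.37 (camera adjusted p = 6.85e-08, adjusted p = 0.358 with an estimated correlation, 0.30 to 0.49 within slides). With replicate number as a block, 44 rose and 1 fell. rrn3, an initiation factor of RNA polymerase I, rose by 1.34 (SE 0.21, adjusted p = 0.00121). utp4 (1.08), rrp9 (0.67) and nmd3 (0.84), which act in small subunit processing and large subunit export, passed as well, but their calls ended when single arrays were left out, for 3, 5 and 7 of the 16 arrays. Ribosomal protein genes had medians of -0.23 for 47 large subunit genes (camera adjusted p = 0.00283, adjusted p = 0.552 with an estimated correlation, -0.26 to -0.17 within slides) and -0.23 for 35 small subunit genes (camera adjusted p = 0.00385, adjusted p = 0.552 with an estimated correlation, -0.28 to -0.14 within slides). Both calls ended with quantile normalization (-0.04 and -0.04, adjusted p = 0.686 and 0.458) and with the deposited table (-0.02 and -0.05, 0.427 and 0.303). A single gene fell in each list and none adjusted over the list alone: rpl9 (-0.50, adjusted p = 0.0466) and rps9 (-0.53, adjusted p = 0.0451), calls that ended when single arrays were left out (13 and 12 of the 16).

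Pancreas genes did not move as a group. Whole embryos were measured, so values of these genes, here and in the later comparisons, cannot be assigned to the pancreas. Of 19 measured endocrine genes, 1 rose and 2 fell (1 and 6 adjusted over the list alone). The list's median was 0.15, its mean -0.07 and its camera direction down (adjusted p = 0.478, -0.07 to 0.12 within slides), while fry found change in either direction (adjusted p = 1.53e-09). The median was below 0 with normexp background (-0.06), without a filter (-0.04) and with a filter on all 16 arrays (-0.10). The members that passed were insm1a (-1.36 ± 0.17, adjusted p = 0.000183, -1.58 to -0.95 within slides) and insm1b (-0.89 ± 0.22, adjusted p = 0.0201), which encode zinc finger factors of endocrine cells and also of neurons, and sox4b (1.31 ± 0.30, adjusted p = 0.0138). The call of insm1b ended in 6 of 27 alternative settings, single arrays left out included. Of 7 measured exocrine genes, 1 rose and 1 fell (1 and 2 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 0.425, fry in either direction adjusted p = 0.0086, -1.12 to 0.34 within slides), and 0.01 without replicate 3 of the Sbds morphants. The elastase gene ela2 fell by 1.41 (SE 0.27, adjusted p = 0.00505, -1.56 to -1.16 within slides), and the trypsin gene prss1 was at 1.03 (adjusted p = 0.0407), a call that ended when single arrays were left out (9 of the 16).

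The 3 pancreas genes named beforehand did not pass over all arrays without the block and passed with it. The insulin gene ins (chromosome 5, 36531424 to 36531483) was at 0.57 ± 0.23 (adjusted p = 0.155, with the block 0.0106, 0.23 to 0.98 within slides). pdx1, a master factor of the pancreas (chromosome 24, 21245921 to 21245980), was at 0.46 ± 0.28 (adjusted p = 0.382, with the block 0.0437, 0.10 to 0.91 within slides). ptf1a, a factor of exocrine precursors (chromosome 2, 27673593 to 27673652), was at -1.33 ± 0.42 (adjusted p = 0.063, with the block 0.0114, -2.23 to -0.75 within slides), and it was above background on 3 of the 4 arrays of each morphant group, so its values in all comparisons are levels near background. It passed with only the groups compared (adjusted p = 0.0458), the deposited table (-0.97, 0.0311), the mean of all probes of a gene (0.0484), and without replicate 4 of the Sbds morphants (-1.57, 0.0493) or replicate 2 of the double morphants (0.0177), and was at -0.40 with normexp background. ins passed without replicate 1 of the controls (0.78, 0.0427). The second probes of ins and pdx1 were at 0.59 ± 0.29 and 0.66 ± 0.36 and did not pass with the block (adjusted p = 0.0632 and 0.0658).

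Markers of other tissues were tested as well. Erythroid genes had a median of -0.51 (1 of 23 rose and 4 fell, 1 and 8 adjusted over the list alone; camera adjusted p = 0.00385, adjusted p = 0.39 with an estimated correlation, -0.49 to -0.16 within slides). Among them alas2, the first enzyme of haem synthesis in red cells, fell by 0.79 (adjusted p = 0.00981), and the embryonic globin gene hbbe2 rose by 1.04 (adjusted p = 0.0128). The lists that did not pass were endoderm, gut and liver (median 0.02, camera adjusted p = 0.96), myeloid (-0.15, 0.478), vascular (-0.07, 0.584) and retina and lens (-0.24, 0.0748). Neither did muscle (0.07, 0.69), neural crest and pigment (-0.21, 0.54), notochord and matrix (0.31, 0.104), epidermis and hatching gland (0.16, 0.0911), and yolk and liver secreted proteins (-0.07, 0.233). With the block, the notochord and matrix list (adjusted p = 0.042) and the epidermis and hatching gland list (adjusted p = 0.0495) passed. The epidermis list also passed with quantile normalization (0.00238), normexp background (0.00631), no filter (0.0461) and the deposited table (0.0064). The notochord list also passed with normexp background (0.00796), a filter on all 16 arrays (0.024), the deposited table (0.0434) and fry (0.0297), and the retina and lens list with no filter (0.0125), only the groups compared (0.0351) and the deposited table (0.0434). The retina and lens list passed without replicates 1 and 2 of the controls (adjusted p = 0.0184 and 0.0342), replicate 4 of the p53 morphants (0.0433) and replicate 1 of the Sbds morphants (0.00484). The notochord and matrix list passed without the latter (0.0496). Single members that passed in these lists included onecut1 (-1.21), notch1b (-0.86), rx2 (-1.54), rbp4 (-0.89) and anxa1a (0.66). Of these, anxa1a lost its call when single arrays were left out (4 of the 16).

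The stress lists did not pass as lists: unfolded protein and integrated stress response (median -0.19, camera adjusted p = 0.169), heat shock and oxidative stress (0.06, 0.478) and interferon and innate response (0.24, 0.111), which passed without replicate 1 of the controls (0.30, 0.0191) and without a filter (0.32, 0.0153). By fry the first of these lists passed (0.0132). Single members passed in both directions. trib3 (-1.04, adjusted p = 0.00174) and phgdh (-1.56, adjusted p = 0.00543) fell, irf9 rose (1.58, adjusted p = 0.000338), and ddit3 was at 0.89 (adjusted p = 0.023), a call that ended when single arrays were left out (5 of the 16). The 10 named genes with the largest rises were led by rspo1, a Wnt agonist (chromosome 16, 32672449 to 32672508), at 4.60 ± 0.37 (adjusted p = 4.65e-06, 4.34 to 5 within slides). They also held the interferon-induced gene isg15 (3.79 ± 0.68), the heat shock gene hsp70.2 (3.44 ± 0.67), bmb (3.41 ± 0.19), the angiotensin-converting enzyme gene ace (3.06 ± 0.23), ltb4r (3.04 ± 0.40), lnx1 (3.02 ± 0.38) and rsrp1 (2.99 ± 0.69), beside gadd45aa and casp8. In total 78 genes changed that were above background on all arrays of only 1 of the groups, 43 of them brighter in Sbds morphants. The cell cycle inhibitor gene cdkn2a/b was at least 15.4-fold higher (adjusted p = 9.89e-07), and dnah7, a dynein of motile cilia, at least 17.5-fold higher (adjusted p = 9.08e-06). Such minima hold for the estimate and leave out its sampling error, here and below.

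With replicate number as a block the count was 9041 (4200 higher, 4841 lower), and it held all 2348. The count fell to 651 with normexp background, to 1484 without a filter, to 1027 with a fold minimum, and to 1533 and 1440 without replicates 2 and 3 of the Sbds morphants. With normexp background the log2 values of 15 of 66 named genes with a call were smaller by over 1.5 times, and 23 calls ended. Among them isg15 was at 2.30, bmb at 2.18, bbc3 at 1.70, ace at 1.44, ltb4r at 1.21, foxn4 at -1.31 and otpa at -1.26. The calls of irf9 (0.64, adjusted p = 0.128) and rx2 (-0.66, 0.116) ended.

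The comparison of double with p53 morphants asks what the Sbds morpholino does when the p53 morpholino is also given. There fewer genes changed, and 6 of 23 p53 target genes rose. bbc3 rose 6.32-fold (2.66 ± 0.20, adjusted p = 4.06e-06, 2.34 to 2.86 within slides). The largest fall was in rpl22l1, a paralog of a large subunit ribosomal protein gene (chromosome 24, 26186927 to 26186986): -2.21 ± 0.27, adjusted p = 0.000751, -2.89 to -1.93 within slides. In total 152 probes changed, 96 higher and 56 lower, standing for 53 named genes higher and 46 lower.

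Of the 23 p53 target genes, 6 rose, none fell and 17 did not pass (9 rose adjusted over the list alone), with a median of 0.35 (camera adjusted p = 3.28e-13, adjusted p = 0.000284 with an estimated correlation, 0.30 to 0.74 within slides). Besides bbc3, ccng1 rose by 2.28 (SE 0.21, adjusted p = 4.45e-05), rps27l by 2.43 (SE 0.24, adjusted p = 9.68e-05) and casp8 by 2.27 (SE 0.27, adjusted p = 0.000504). mdm2 was at 1.65 ± 0.29 (adjusted p = 0.0164, 1.43 to 1.95 within slides), a call that ended when single arrays were left out (5 of the 16). Its second probe was at 1.68 ± 0.14 (adjusted p = 2.27e-05). gadd45aa was at 1.25 (adjusted p = 0.0568, with the block 0.00237) and baxa at 0.82 ± 0.28 (adjusted p = 0.297, with the block 0.00403). The count of 6 is therefore one without the block. Of 27 apoptosis genes, bbc3 and casp8 rose and none fell, the same 2 adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.0046, adjusted p = 0.0328 with an estimated correlation, 0.05 to 0.17 within slides), and 0.08 and 0.07 without replicate 2 of the p53 and of the double morphants. It was 0.06 with normexp background, 0.07 with the mean of all probes of a gene and 0.23 with the deposited table.

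Ribosome biogenesis genes had a median of 0.34 (camera adjusted p = 6.48e-13, adjusted p = 0.25 with an estimated correlation, 0.13 to 0.59 within slides). Without replicate 4 of the p53 morphants the median was 0.19. None of the 90 passed over all probes or adjusted over the list alone, and 29 rose with the block. Ribosomal protein genes had medians of -0.20 for the large subunit (camera adjusted p = 0.000534, adjusted p = 0.45 with an estimated correlation, -0.39 to 0.01 within slides) and -0.22 for the small subunit (camera adjusted p = 0.000431, adjusted p = 0.448 with an estimated correlation, -0.38 to 0.08 within slides), but the large subunit median turned to 0.01 with quantile normalization, where the small subunit median was -0.07. Both calls ended there (adjusted p = 0.884 and 0.212), and the large subunit call also ended with the deposited table (-0.01, 0.195). Without replicate 2 of the double morphants the medians were -0.31 and -0.34, without their replicate 3 the former was -0.12, and without replicate 1 of the p53 morphants the latter was -0.15. No ribosomal protein gene of either list passed over all probes, and 1 small subunit gene fell adjusted over the list alone.

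Cell cycle genes had a median of -0.28 (3 of 36 fell, 7 adjusted over the list alone; camera adjusted p = 2.79e-07, adjusted p = 0.268 with an estimated correlation, -0.40 to -0.25 within slides). The 3 were mcm7 (-0.70, adjusted p = 0.0344), gmnn (-0.74, adjusted p = 0.0364) and ccne2 (-0.99, adjusted p = 0.0431), whose calls ended when single arrays were left out (9, 14 and 14 of the 16). The 30 neural genes did not pass as a list (median -0.09, camera adjusted p = 0.483, -0.24 to 0.07 within slides), and none passed singly. With the block 5 neural genes fell, among them neurod4 (-0.46, with the block adjusted p = 0.037).

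Pancreas lists did not pass: endocrine (median 0.08, camera adjusted p = 0.483, -0.13 to 0.12 within slides) and exocrine (-0.28, 0.0949, -0.60 to -0.09 within slides). The endocrine median was -0.03 without replicate 3 of the p53 morphants. No endocrine gene changed over all probes or adjusted over the list alone, and no exocrine gene over all probes. insm1a was at -0.44 (adjusted p = 0.36, with the block 0.0378) and ela2 at -1.14 (adjusted p = 0.0956, with the block 0.000548), the latter being the 1 exocrine gene that fell adjusted over the list alone. ins was at 0.18 ± 0.23 (adjusted p = 0.887), pdx1 at 0.08 ± 0.28 (adjusted p = 0.975) and ptf1a at -0.28 ± 0.42 (adjusted p = 0.915).

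The unfolded protein and integrated stress response list had a median of -0.40 (2 of 29 fell; 1 rose and 9 fell adjusted over the list alone; camera adjusted p = 0.000301, adjusted p = 0.0104 with an estimated correlation, -0.49 to -0.12 within slides). That median was -0.23 with normexp background and -0.20 with the deposited table, with the call kept. The chaperone gene hsp90b1 fell 2.14-fold (SE 0.18 on the log2 scale, adjusted p = 0.0113, -1.93 to -0.54 within slides), and the disulfide isomerase gene pdia6 was at -0.74 (adjusted p = 0.0331), a call that ended when single arrays were left out (8 of the 16). Erythroid genes had a median of -0.48 (1 of 23 fell; 1 rose and 5 fell adjusted over the list alone; camera adjusted p = 8.42e-05, adjusted p = 0.25 with an estimated correlation, -0.43 to -0.26 within slides), and -0.26 with normexp background. The gene that passed was tspo (-1.13, adjusted p = 0.0337), whose call ended when single arrays were left out (8 of the 16).

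Retina and lens genes had a median of -0.57 with no single gene past the test over all probes or adjusted over the list alone (camera adjusted p = 0.000172, adjusted p = 0.448 with an estimated correlation, -1.06 to 0.06 within slides). Without replicate 4 of the p53 morphants that call ended (-0.38, adjusted p = 0.0536), and with normexp background the median was -0.28. Myeloid genes (-0.20, camera adjusted p = 0.0448, adjusted p = 0.448 with an estimated correlation) and interferon genes (0.25, camera adjusted p = 0.0315, adjusted p = 0.448 with an estimated correlation) passed, but not with the block (adjusted p = 0.129 and 0.0556). The myeloid call also ended when single arrays were left out (8 of the 16), with a median of -0.09 and an adjusted p of 0.0848 without replicate 3 of the double morphants. Across all 27 alternative settings, these included, the myeloid call ended in 16. The interferon call ended without replicate 1 of the double morphants (0.15, 0.235) and replicates 2 and 4 of the p53 morphants (0.10, 0.0684 and 0.14, 0.0536). Across all 27 alternative settings, these included, the interferon call ended in 8 and its median was as low as 0.03. The interferon gene irf9 was at 1.08 (adjusted p = 0.0323), a call that ended when single arrays were left out (9 of the 16). The lists that did not pass were endoderm, gut and liver (0.09, 0.707), vascular (-0.10, 0.305) and muscle (-0.04, 0.295). Nor did neural crest and pigment (-0.25, 0.0522), notochord and matrix (0.08, 0.295), epidermis and hatching gland (0.00, 0.972), yolk and liver secreted proteins (-0.03, 0.702), and heat shock and oxidative stress (-0.03, 0.877). The neural crest and pigment list passed with no filter (0.0322), a filter on all 16 arrays (0.04) and trend and robust (0.0432). It also passed without replicate 1 of the double morphants (0.0334) and replicates 2 and 3 of the p53 morphants (0.0422 and 0.0405).

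Other genes with large rises were bmb (3.20 ± 0.19, adjusted p = 4.08e-07), lnx1 (2.48 ± 0.38), exo5, a DNA exonuclease gene (2.27 ± 0.22), the phosphoinositide kinase subunit gene pik3r3a (1.75 ± 0.15) and rasl11b (1.68 ± 0.22). Other falls were in arhgap17b (-2.11 ± 0.32, adjusted p = 0.0059), samd8 (2.46-fold lower), hoga1 (-1.51), the parvalbumin gene pvalb3 (-1.27), pdk2a (-1.18), pdgfra (-1.02) and ivns1abpa (-1.01). The calls of hoga1, pvalb3, pdk2a, pdgfra and ivns1abpa ended when single arrays were left out (7, 2, 1, 14 and 2 of the 16). In total 14 genes changed that were above background on all arrays of only 1 of the groups, 6 of them brighter in double morphants. rspo1 was at least 19.4-fold higher (adjusted p = 2.25e-05) and rbl2, a gene of the retinoblastoma family, at least 7.32-fold higher (adjusted p = 0.000138).

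With replicate number as a block the count was 2522 (1162 higher, 1360 lower), and 46.1% of these were higher in place of 63.2%. The count was 37 with normexp background, 91 without a filter and 54 with only the groups compared. It was between 82 and 98 without any of the 4 p53 morphant arrays, 96 and 87 without replicates 2 and 3 of the double morphants, and 260 without their replicate 1 (125 higher, 135 lower). With normexp background the log2 values of 9 of 26 named genes with a call were smaller by over 1.5 times, and 15 calls ended. bmb was at 1.69, lnx1 at 1.58, exo5 at 1.46, bbc3 at 1.31 and rasl11b at 0.90. The calls of arhgap17b (-1.38, adjusted p = 0.186), samd8 (-0.85, 0.151), pdk2a (-0.46, 0.924) and irf9 (0.33, 1) ended, and samd8 also lost its call with the mean of all probes of a gene (-0.71, 0.168).

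In p53 morphants compared with control embryos, which asks what the p53 morpholino does alone, no gene passed the test. limma called 0 probes at an adjusted p under 0.05, without and with the block. Of 28324 tested, 173 and 959 had an unadjusted p under 0.05. Both are below the share of 0.05 that chance alone would give, and without the block slide differences stay in the residual. The lack of calls therefore does not show that the p53 morpholino alone did nothing. With the block the smallest adjusted p was 0.0528. The named genes with the smallest p were rspo1, bmb (-0.75 ± 0.19), ccrl1a, entr1 and anxa1b (-0.54 ± 0.17), each with an adjusted p of 1. No size is given for rspo1, ccrl1a and entr1, which were not above background on all p53 morphant arrays. mdm2 was at -0.65 ± 0.29, lower on all 4 slides, and at -0.57 ± 0.14 in its second probe (adjusted p = 1 for both), and ins, pdx1 and ptf1a were at 0.05, -0.17 and -0.23. Among other p53 target genes, ccng1 was at -0.66 ± 0.21, bbc3 at -0.58 ± 0.20 and baxa at -0.01 ± 0.28. As a list, p53 target genes were lower (median -0.05, camera adjusted p = 1.68e-05, adjusted p = 0.0183 with an estimated correlation, -0.27 to -0.08 within slides), but not with the block and an estimated correlation (0.0706) or by fry without it (0.262). Ribosome biogenesis genes were higher (0.10, camera adjusted p = 4.47e-07, adjusted p = 0.447 with an estimated correlation, 0.01 to 0.15 within slides). Single arrays moved these small medians from -0.18 to -0.04 and from 0.02 to 0.24, with both calls kept. No member of any list passed over all probes or adjusted over the list alone. Retina and lens genes (-0.14, camera adjusted p = 0.0216, adjusted p = 0.893 with an estimated correlation) and interferon genes (-0.16, camera adjusted p = 0.0337, adjusted p = 0.506 with an estimated correlation) passed but not with the block, where both had an adjusted p of 0.0961. The retina and lens call ended without replicates 1 and 2 of the p53 morphants (adjusted p = 0.445 and 0.332) and replicates 3 and 4 of the controls (0.128 and 0.879), and its median was 0.02 without replicate 3 of the p53 morphants. The interferon call ended without replicate 1 of the controls (0.713) and replicates 2 and 4 of the p53 morphants (0.308 and 0.175). Across all 27 alternative settings, these included, it ended in 10, with medians from -0.29 to -0.02. The other 18 lists had camera adjusted p from 0.0565 to 0.9.

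The comparison of double with Sbds morphants asks what the p53 morpholino changes when the Sbds morpholino is also given. There 5 of 30 neural and 2 of 36 cell cycle genes rose and 3 of 23 p53 target genes fell. The rises as lists were not past the test with an estimated correlation (adjusted p = 0.0843 and 0.117). plp1a rose by 2.93 (SE 0.51, adjusted p = 0.0152, 2.60 to 3.25 within slides), her4.4 by 2.24 (SE 0.40, adjusted p = 0.019) and the neural repressor gene her3 by 1.71 (SE 0.29, adjusted p = 0.0121). gadd45aa fell by 2.61 (SE 0.27, adjusted p = 0.000398, -3.25 to -2.01 within slides), ace fell by 2.24 (SE 0.23, adjusted p = 0.000366) and the heat shock gene hsp90aa1.2 fell by 2.78 (SE 0.43, adjusted p = 0.009). In total 267 probes changed, 128 higher and 139 lower. helt (1.73), otpb (1.61), isg15 (-3.32) and rspo1 (-1.79) passed too, but lost their call when single arrays were left out (5, 15, 8 and 7 of the 16), plp1a without 1 and her4.4 without 3.

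Of 30 neural genes, 5 rose and none fell (12 rose adjusted over the list alone), with a median of 0.58 (camera adjusted p = 1.16e-08, adjusted p = 0.0843 with an estimated correlation, 0.40 to 0.62 within slides). The proneural gene ascl1b rose by 1.23 (adjusted p = 0.00749), dlb by 0.78 (adjusted p = 0.0184) and nova2 by 0.73 (adjusted p = 0.0289). Of 36 cell cycle genes, mcm7 (0.67, adjusted p = 0.0335) and mcm6 (0.72, adjusted p = 0.0339) rose and none fell (12 rose adjusted over the list alone), with a median of 0.40 (camera adjusted p = 8.16e-12, adjusted p = 0.117 with an estimated correlation, 0.36 to 0.51 within slides). Of 23 p53 target genes, 3 fell and none rose (8 fell adjusted over the list alone), with a median of -0.36 (camera adjusted p = 6.56e-06, adjusted p = 0.0155 with an estimated correlation, -0.48 to -0.34 within slides). Beside gadd45aa they were casp8 (-1.31, adjusted p = 0.0326) and mdm2 (-1.35, adjusted p = 0.0419, and -1.35 ± 0.14, 0.000449 in its second probe). With the block bbc3 (-0.79, adjusted p = 0.0146) and baxa (-0.58, 0.0133) passed as well. Of 27 apoptosis genes, casp8 and bcl2l1 fell (5 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.00364, adjusted p = 0.0267 with an estimated correlation, -0.40 to -0.14 within slides), and -0.32 without replicate 4 of the double morphants. Single arrays ended the calls of dlb (4 of 16), nova2 (5), mcm7 (7), mcm6 (9), casp8 (9), the first probe of mdm2 (12) and bcl2l1 (11). Those fits had no block. With the block over all arrays, 0 of the 23 calls of named genes in this comparison ended.

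Of 19 endocrine genes, insm1a (0.86, adjusted p = 0.0254) and nkx2.2a (0.65, adjusted p = 0.0335) rose (4 adjusted over the list alone), and the list did not pass (median 0.00, camera adjusted p = 0.167). pdx1 was at -0.55 ± 0.28 (adjusted p = 0.461, with the block 0.0396), ins at -0.34 ± 0.23 (adjusted p = 0.618) and ptf1a at 0.82 ± 0.42 (adjusted p = 0.445). The second probe of pdx1 was at -0.16 ± 0.36 and did not pass with the block (adjusted p = 0.709). The calls of insm1a and nkx2.2a ended when single arrays were left out (5 and 10 of the 16). Lists with a camera adjusted p just under the threshold were retina and lens (-0.34, 0.0437, adjusted p = 0.775 with an estimated correlation), epidermis and hatching gland (-0.17, 0.0436, adjusted p = 0.451 with an estimated correlation) and unfolded protein and integrated stress response (-0.24, 0.0436, adjusted p = 0.0902 with an estimated correlation). The median of the last was -0.10 with normexp background. With the block the adjusted p was 0.0644, 0.0143 and 0.0723, and muscle genes passed as well (-0.20, with the block 0.0143). The retina and lens call ended without replicate 1 of the Sbds morphants (-0.15, 0.34) and replicates 2 and 3 of the double morphants (-0.39, 0.156 and -0.19, 0.227). The epidermis call ended without replicates 3 and 4 of the Sbds morphants (0.123 and 0.053) and replicates 1, 3 and 4 of the double morphants (0.054, 0.0926 and 0.0928, with a median of -0.11 without replicate 3). The unfolded protein call ended without replicates 3 and 4 of the Sbds morphants (0.123 and 0.22) and replicate 1 of the double morphants (0.221). The other 15 lists, ribosomal protein and ribosome biogenesis genes included, had camera adjusted p from 0.0586 to 0.986. In total 16 genes changed that were above background on all arrays of only 1 of the groups, all brighter in Sbds morphants. cdkn2a/b was at least 8.76-fold lower in double morphants (adjusted p = 0.000191). foxj1b, a factor of motile cilia, was 2.86-fold lower (adjusted p = 0.000398), where the bound equals the estimate.

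With the block the count was 4207 (2282 higher, 1925 lower). More probes were also higher than lower with quantile normalization (143 and 137), a filter on all 16 arrays (143 and 128), the deposited table (150 and 149), without replicate 1 of the Sbds morphants (126 and 71) and without replicate 3 of the double morphants (147 and 112). It was 99 with normexp background, 94 without a filter, 13 with only the groups compared and 146 with a fold minimum. It was 77, 101 and 142 without replicates 2, 3 and 4 of the Sbds morphants, and 126 and 99 without replicates 1 and 4 of the double morphants. With normexp background 11 of 23 calls of named genes ended, with dlb at 0.44 (adjusted p = 0.704), and ace was at -1.19.

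The comparison of double morphants with control embryos asks what stays changed with both morpholinos. There 5 of 23 p53 target genes were higher and 4 of 29 genes of the unfolded protein and integrated stress response lower. bbc3 rose by 2.08 (SE 0.20, adjusted p = 0.000109) and rspo1 by 2.81 (SE 0.37, adjusted p = 0.00201). rpl22l1 fell by 2.26 (SE 0.27, adjusted p = 0.00106), arhgap17b fell by 2.16 (SE 0.32, adjusted p = 0.0062). hsp90b1 fell by 1.31 (SE 0.18, adjusted p = 0.00342). In total 204 probes changed, 97 higher and the rest lower. bmb (2.46) and exo5 (1.88) were among the largest rises, and pfkma (-1.50), hoga1 (-1.40) and the calsequestrin gene casq1a (-1.34) among the largest falls, with calls that ended when single arrays were left out (11, 14 and 9 of the 16) for these 3. mdm2 was at 1.00 ± 0.29 (adjusted p = 0.156, with the block 0.00165) and passed in its second probe (1.12 ± 0.14, adjusted p = 0.00201). ins was at 0.23, pdx1 at -0.08 and ptf1a at -0.51 (adjusted p = 0.787, 0.965 and 0.713).

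Of 23 p53 target genes, 5 rose (9 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 5.41e-10, adjusted p = 0.00127 with an estimated correlation, 0.25 to 0.51 within slides), among them ccng1 (1.62) and rps27l (1.81). With the block baxa (0.81, adjusted p = 0.00329) and the first probe of mdm2 (1.00, 0.00165) passed as well. The unfolded protein and integrated stress response list had a median of -0.45 (4 of 29 fell, 8 adjusted over the list alone; camera adjusted p = 6.45e-05, adjusted p = 0.00529 with an estimated correlation, -0.60 to -0.22 within slides), and -0.26 without replicate 1 of the double morphants, -0.25 with normexp background and -0.26 with the deposited table. Ribosome biogenesis genes had a median of 0.45 (none passed, 2 rose adjusted over the list alone, 45 rose with the block; camera adjusted p = 5.76e-20, adjusted p = 0.114 with an estimated correlation, 0.26 to 0.58 within slides). The ribosomal protein medians were -0.19 and -0.22 (camera adjusted p = 0.00206 and 0.00168, adjusted p = 0.5 for both with an estimated correlation), and -0.30 and -0.34 without replicate 2 of the double morphants. Without replicates 3 and 4 of that group the former was -0.10 and -0.12. Both calls ended with quantile normalization (-0.01 and -0.06, adjusted p = 0.815 and 0.251), and that of the large subunit with the deposited table (-0.03, 0.0832). Cell cycle (-0.33, 9.02e-07), erythroid (-0.44, 4.4e-05), retina and lens (-0.52, 2.82e-06) and myeloid genes (-0.22, 0.0151) were lower, with adjusted p = 0.334, 0.23, 0.393 and 0.393 with an estimated correlation. With normexp background the last 3 medians were -0.28, -0.30 and -0.12. The myeloid call ended with the block (adjusted p = 0.0724) and without replicate 3 of the controls (0.0782). The neutrophil genes mpx and lyz were lower (adjusted p = 0.00963 and 0.0472), with no size given because neither was above background on all double morphant arrays, the latter with a call that ended when single arrays were left out (15 of the 16). The other 13 lists did not pass, with neural genes at -0.15 (0.198) and apoptosis genes at 0.06 (0.0506).

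With the block the count was 3544 (1569 higher, 1975 lower). Without it 22 genes changed that were above background on all arrays of only 1 of the groups. cabp2a was at least 3.47-fold lower (adjusted p = 0.000488). tph2 was 3.8-fold higher (adjusted p = 0.00106), where the bound equals the estimate. The count was 44 with normexp background (30 higher), 91 without a filter (56 higher), 41 with only the groups compared (29 higher) and 134 with a fold minimum (70 higher). It was 449, 120, 98 and 121 without replicates 1 to 4 of the double morphants (150, 56, 58 and 63 higher). It was 92, 81 and 94 without replicates 2, 3 and 4 of the controls (60, 51 and 51 higher). With normexp background 11 of 21 calls of named genes ended, among them arhgap17b (-1.43, adjusted p = 0.119), pfkma (-0.79, 0.163), mpx and lyz (0.11 and 0.344), and rspo1 was at 1.66, bmb at 1.53 and bbc3 at 1.16.

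The Sbds effects with and without the p53 morpholino mostly shared a direction among called probes. How far they differed in size depended on the probes chosen. Across the 28324 tested probes, which are not independent replicates, the effects correlated with Pearson r 0.62 and Spearman rho 0.57, and 70.6% had the same sign. Within slides 1 to 4, where each effect rests on a single pair of arrays, Pearson r was 0.14, 0.38, 0.69 and 0.57. Of the 96 probes higher in double morphants than in p53 morphants, 95 were also higher in Sbds morphants than in control embryos, where independence would give 3.4. Of the 56 lower probes 47 were shared, where independence would give 2.7. Among the 152 probes changed in double morphants, the median absolute effect was 1.40 there and 1.71 in Sbds morphants (median ratio 0.87, smaller for 68.4%). Among the 2348 probes changed in Sbds morphants, it was 0.92 there and 0.40 in double morphants (median ratio 0.43), and each set favours the comparison it was chosen from. For the 2522 probes called with the block in double morphants the median ratio was 0.95, smaller for 51.2%.

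**Figure D3:**
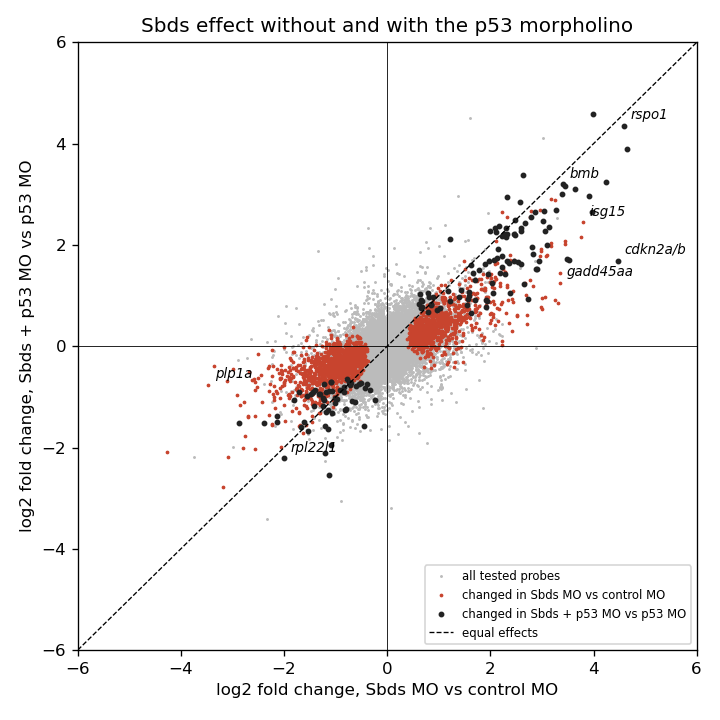
Sbds effect without the p53 morpholino (x axis, log2 fold change of Sbds morphants over control embryos) against the Sbds effect with it (y axis, log2 fold change of double over p53 morphants) for the 28324 tested probes. Red points changed in the first comparison (2348), black points in the second (152), and the dashed line marks equal effects.

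The interaction, which tests the difference between these effects, passed for 1 probe in limma, with 1408 at an unadjusted p under 0.05. That is about the share of 0.05 that chance alone would give over the 28324 tested. With the block 5094 were under it. The probe that passed without the block, A_15_P267357 (chromosome 11, 41807854 to 41807913), has no gene name and was named here after its value was seen. It was at -3.35 in Sbds morphants over control embryos (adjusted p = 1.39e-06) and at -0.40 in double over p53 morphants (adjusted p = 0.652). This is a difference of 2.95 ± 0.34 (adjusted p = 0.011). No named gene passed. The smallest p were those of ace (-2.09 ± 0.32, adjusted p = 0.0557), foxi1 (-1.48 ± 0.24, adjusted p = 0.0819) and mapk12b (1.00 ± 0.18, adjusted p = 0.162), which all passed with the block (adjusted p = 0.0166, 0.000824 and 0.0123). cdkn2a/b and foxj1b were among them, but neither was above background on all double morphant arrays, so their sizes are not given. mdm2 was at -0.70 ± 0.41 (adjusted p = 1, with the block 0.0897) and at -0.78 ± 0.20 in its second probe (adjusted p = 0.45, with the block 0.0417).

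Among lists, the fall of neural genes was smaller with the p53 morpholino (difference 0.56, camera adjusted p = 1.33e-10, adjusted p = 0.114 with an estimated correlation, 0.41 to 0.61 within slides, 6 genes adjusted over the list alone). The fall of cell cycle genes was smaller too (0.40, camera adjusted p = 3.74e-11, adjusted p = 0.168 with an estimated correlation, 0.36 to 0.60 within slides). With the block both kept a p under the threshold with an estimated correlation (adjusted p = 0.0317 for each), and 8 neural and 4 cell cycle genes passed singly, among them dlb (0.94, with the block adjusted p = 0.0141), ascl1b (1.27, 0.0274) and mcm6 (0.63, 0.0247). The rise of p53 target genes was smaller (-0.24, camera adjusted p = 0.00983, adjusted p = 0.114 with an estimated correlation, -0.36 to -0.14 within slides), a call that ended without replicate 1 of the double morphants (adjusted p = 0.0626) and replicate 4 of the p53 morphants (0.0568). Its median was -0.14, -0.16 and -0.08 without replicate 2 of the p53 morphants, replicate 2 of the Sbds morphants and replicate 4 of the controls. Among them gadd45aa passed with the block (-2.09, adjusted p = 0.162, with the block 0.00503). Not all members moved this way. ccng1 was at 0.29 (with the block adjusted p = 0.439), with its other probes from -0.11 to 0.24, and bbc3 at -0.21 (0.691). ccng1 rose by 1.98 in Sbds morphants over control embryos and by 2.28 in double over p53 morphants. Epidermis genes were at -0.20 (camera adjusted p = 0.0426, adjusted p = 0.524 with an estimated correlation), a call that ended when single arrays were left out (8 of the 16). The other 18 lists did not pass (camera adjusted p from 0.0532 to 0.929). Ribosome biogenesis genes were at -0.02 (0.776), large and small ribosomal protein genes at 0.01 (0.7) and -0.01 (0.776), and endocrine and exocrine pancreas genes at 0.05 (0.135) and -0.17 (0.781). insm1a was at 0.93 (adjusted p = 0.424, with the block 0.0229).

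**Figure D4:**
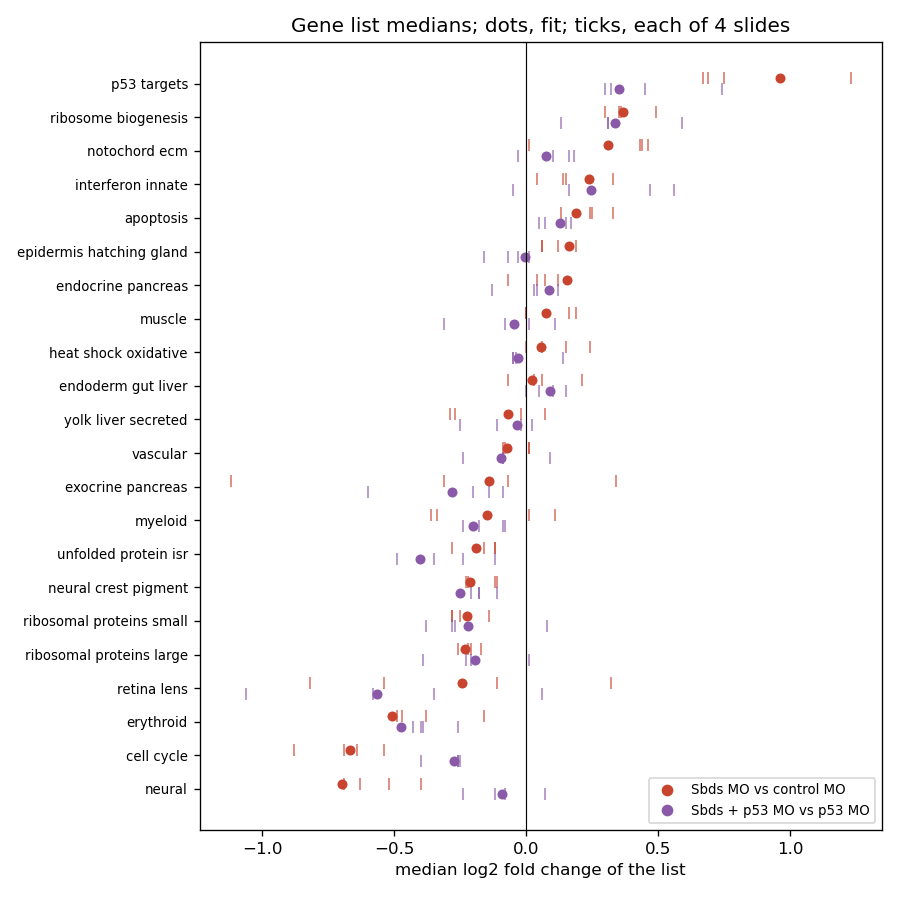
Median log2 fold change (x axis) of each of the 22 gene lists (y axis) for Sbds morphants over control embryos (red) and double over p53 morphants (purple). Dots are the median of the fitted changes and ticks the median on each of the 4 slides. p53 target genes were at 0.96 and 0.35, neural genes at -0.70 and -0.09 and ribosome biogenesis genes at 0.37 and 0.34. Large subunit ribosomal protein genes were at -0.23 and -0.20, the latter at 0.01 with quantile normalization.

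With the block 476 probes passed the interaction (324 higher, 152 lower). The count was 6 with a filter on all 16 arrays, 4 with normexp background, 4 with trend and robust, and 2 with the deposited table. It was 8 without replicate 4 of the p53 morphants, 3 without replicate 4 of the Sbds morphants, and 2 and 2 without replicates 2 and 3 of the double morphants.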

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

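Of the tests in this part, 3 were chosen only after the result was seen: those of a uniformly weaker Sbds knockdown, of p53 activity left under the p53 morpholino, and of p53-dependent loss of neural transcripts.

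Among 220 groups of 4 arrays tested, covering 52 genes and the array measures, 17 held an array far from the other 3, and chance alone gives such an array in about 1 in 20 groups. The median negative-control signal was 25.79 on control replicate 1 (others 19.62 to 20.4) and 44.45 on double morphant replicate 1 (others 19.53 to 22.14). The log2 level of rspo1 was -1.157 on double morphant replicate 1 (others 0.422 to 0.727), and that of isg15 was -0.032 on control replicate 1 (others -4.028 to -3.381). In Sbds morphants, gadd45aa was at 1.536 on replicate 3 (others 0.917 to 0.971), rasl11b at 0.557 on replicate 3 (0.039 to 0.062), ltb4r at -1.684 on replicate 4 (-0.806 to -0.702) and cdkn2a/b at -1.382 on replicate 4 (-0.988 to -0.91). In p53 morphants, otpa was at -0.978 on replicate 3 (-0.187 to -0.103), anxa1b at 1.511 on replicate 4 (1.983 to 2.064) and cdkn2a/b, not above background in this group, at -6.869 on replicate 4 (-5.859 to -5.825). In double morphants, ptf1a was at -5.179 on replicate 2 (-3.594 to -3.268), exo5 at 0.802 on replicate 2 (-0.201 to -0.145) and pdk2a at -3.201 on replicate 3 (-2.531 to -2.423). In control embryos, pdx1 was at 0.388 on replicate 2 (-0.555 to -0.5), her3 at 0.532 on replicate 2 (0.012 to 0.088) and casq1a at 1.063 on replicate 1 (0.743 to 0.789).

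The Sbds effect differed with and without the p53 morpholino, by the interaction test, for the unnamed probe A_15_P267357 (2.95, adjusted p = 0.011). With the preset correlation it also differed for the lists of p53 target genes (-0.235), cell cycle genes (0.404), neural genes (0.564) and epidermis and hatching gland genes (-0.203). None of these 4 lists passed with an estimated correlation (adjusted p = 0.114, 0.168, 0.114 and 0.524) without the block. With it, the neural and cell cycle lists did (adjusted p = 0.0317 for each).

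Fewer probes changed with the Sbds morpholino when the p53 morpholino was also given (152 against 2348). The tables argue against the dim array, double morphant replicate 2, as the whole reason. Without it the count was 96, against 2747 for Sbds morphants over control embryos in the same fit. Fewer arrays also lower a count, so the test cannot show how many changes that array hid. A uniformly weaker Sbds knockdown in the co-injected embryos would scale all effects alike only if every transcript followed the knockdown in proportion. Such a common scaling is argued against. The ratio of the second effect to the first was higher in the ribosome biogenesis list than in the neural list on every slide. The gap was at least 0.55 (mean 0.74, SD 0.16, n = 4 slides). The ratio of the cell cycle list (0.3 to 0.62) was exceeded by that of the biogenesis list (0.37 to 1.2) on 3 of 4 slides, so the argument rests on the neural list. The test speaks only to a scaling common to both lists, which were chosen after their values were seen. A weaker knockdown that transcripts do not follow in proportion stays open, because Sbds protein was not measured. A smaller Sbds effect with the p53 morpholino may account for part of the difference: over the 152 probes the median ratio was below 1 on 4 of 4 slides (0.785, 0.919, 0.846 and 0.838). Over the 2522 probes called with the block, the median ratio was closer to equal effects, at 0.947, and 51.2% were smaller.

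Transcripts of p53 target genes were higher with the Sbds morpholino also under the p53 morpholino. An exchange of double morphant arrays with Sbds morphant arrays is argued against, since the list was lower in double than in Sbds morphants on all 4 slides, with -0.34 the highest slide median. A candidate explanation is p53 activity left under the p53 morpholino, because the list's median was -0.364 in double over Sbds morphants (with the block adjusted p = 2.08e-05) and 0.353 in double over p53 morphants (with the block adjusted p = 1.01e-08). Regulation of these genes without p53 was not tested and stays open.

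With the Sbds morpholino 10 of 30 neural genes fell. A general delay of development cannot be told apart from a specific loss, because only 1 of 3 lists that a delay would lower had a median below 0 on all 4 slides: erythroid (-0.49 to -0.16), against muscle (0 to 0.19) and retina and lens (-0.82 to 0.32). A p53-dependent loss of neural transcripts may contribute, since the neural list was higher by 0.584 in double than in Sbds morphants (with the block adjusted p = 1.58e-07), but that call is lost with an estimated correlation (adjusted p = 0.0843, with the block 0.0516). Whether cells died or failed to form was not measured.

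The arrays were regrouped in every other way to ask how often as many probes changed, over 28016 probes with values on all arrays. Over all splits, which ignore that the slides pair the arrays, some shares were under the bound of 1 in 20 set beforehand. These were the shares for double over p53 morphants (1 of 35, 152 probes against at most 0) and for double morphants over control embryos (1 of 35, 204 against at most 0). Most of the splits do not part all pairs and so also move slide differences, so these shares do not exclude chance. For Sbds morphants over control embryos 2 of 35 splits gave as many (2332 against 4728), and for double over Sbds morphants 2 of 35 (266 against 4459), so these counts alone do not exclude chance. For p53 morphants over control embryos 35 of 35 did (0 against 11105). The split with more probes in these 3 cases parts slides 1 and 2 from slides 3 and 4, a structure of the arrays that the first principal component also follows (51.3% of the variance). With slide as a block, which keeps the pairs, only 8 splits part as many pairs, too few for a share under 0.05: the real splits gave 8940, 2488, 4140 and 3501 probes for Sbds morphants over control embryos, double over p53 morphants, double over Sbds morphants and double morphants over control embryos, and the highest others 0, 1, 1 and 0. For the interaction 2 of 100 drawn regroupings gave as many, but the real value was 1 and the highest other also 1. A count of 1 that a regrouping equals cannot be ranked above it, so that bound is not used there and chance is not excluded by it. With the block and draws within slides, which keep the pairs, 1 of 100 gave as many (474 probes against 20). These draws shuffle all group labels, so they assume no group effect at all. They cannot show how often as many probes would pass with an Sbds effect but no interaction, so chance is not excluded.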

How the results depend on the processing

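No test in this part was added after the results were seen. The scan of each slide matches its replicate number, so a scan block is the replicate block and was not run separately. Array position on the slide matches the group, so no setting can part them. Signal over background limits what was tested: 55.0% to 76.5% of probes were well above background on an array. No setting moved the median of all probes by more than 0.0752. For p53 morphants over control embryos the count was 0 in every setting. Directions and calls below that changed are given with their values, and the cause was not tested except where fewer arrays or a fold minimum make a count smaller by construction.

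Counts of changed probes are given for Sbds morphants over control embryos (S), double over p53 morphants (DP), double over Sbds morphants (DS), double morphants over control embryos (DC) and the interaction (I), in that order. Normexp background gave 651, 37, 99, 44 and 4. No filter on dim probes gave 1484, 91, 94 and 91 for S to DC, and the filter on all 16 arrays gave 6 for the interaction. The replicate block gave 9041, 2522, 4207, 3544 and 476, and as a random effect 8566, 2443, 3894, 3418 and 441. With only the groups compared the counts of DP, DS and DC were 54, 13 and 41. eBayes with trend and robust gave 4 for the interaction, the authors' processed values 2, and a fold change minimum 1027, 146 and 134 for S, DS and DC. Without single replicates the ranges were 1440 to 2747, 82 to 260, 77 to 260, 81 to 449 and 1 to 8, and the correlation of the Sbds effects ran from 0.5219 to 0.6799.

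For the lists in Sbds morphants over control embryos, quantile normalization gave -0.04373 and -0.04408 for large and small ribosomal proteins and 0.04851 for yolk, and the authors' processed values -0.02016, -0.0466 and 0.07026, with 0.0441 for vascular. Normexp background gave -0.05581 for endocrine pancreas, -0.04129 for endoderm and -0.02861 for interferon, no filter -0.04371 and -0.01189 for endocrine pancreas and endoderm, and the filter on all 16 arrays -0.09628 for endocrine pancreas. For double over p53 morphants, quantile normalization gave 0.01212 and -0.06502 for large and small ribosomal proteins, 0.001963 for muscle, 0.08986 for epidermis, 0.07135 for yolk and 0.04653 for heat shock. Median centring gave 0.007066 for epidermis. The authors' processed values gave -0.01465 for large ribosomal proteins, 0.05921 for muscle, 0.0901 for epidermis and 0.01989 for heat shock, and the mean of all probes of a gene 0.02533 for epidermis and 0.01014 for heat shock.

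Camera with an estimated correlation gave adjusted p of 0.552, 0.552 and 0.358 in S, and 0.45, 0.448 and 0.25 in DP, for large ribosomal proteins, small ribosomal proteins and ribosome biogenesis. fry gave 0.12 and 0.12 for the ribosomal proteins in S, and 0.177, 0.147 and 0.0776 in DP. fry in either direction gave 0.222 and 0.222 in S, and 0.258, 0.258 and 0.122 in DP, and for endocrine and exocrine pancreas in S 1.53e-09 and 0.0086. Of 136 calls of named genes, 68 ended with only the groups compared, 60 with normexp background, 49 with no filter, 26 with the authors' processed values, 22 with the mean of all probes of a gene, 18 with quantile normalization, 11 with median centring, 1 with trend and robust, and none with the block. Among single genes, ccrl1a in p53 morphants over control embryos was at 0.005264 with normexp background. With the mean of all probes of a gene, ins was at -0.0225 in p53 morphants over control embryos and pdx1 at 0.2112 in DC.

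Without single replicates, list medians that changed sign ranged in S from -0.3744 to 0.01055 for exocrine pancreas, -0.07074 to 0.02763 for endoderm, -0.1415 to 0.03585 for vascular, -0.01541 to 0.1022 for muscle and -0.1884 to 0.02712 for yolk. In DP they ranged from -0.03333 to 0.1634 for endocrine pancreas, -0.04295 to 0.1094 for endoderm, -0.1244 to 0.04729 for epidermis, -0.1606 to 0.01712 for yolk and -0.09662 to 0.03446 for heat shock. In p53 morphants over control embryos retina and lens ranged from -0.317 to 0.01847. Genes that changed sign ranged in DP from -0.5178 to 0.1609 (ptf1a) and -0.06108 to 0.2902 (pdx1). In p53 morphants over control embryos they ranged from -0.4439 to 0.006725 (ptf1a), -0.3752 to 0.06032 (pdx1) and -0.08327 to 0.259 (ins). In DC pdx1 ranged from -0.1921 to 0.145.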

Other observations

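Several members of the lists changed in Sbds morphants over control embryos beside those already named. Among p53 target genes, foxo3b rose by 1.94 (adjusted p = 0.00168), sesn1, a stress-induced regulator of growth signalling, by 0.96 (adjusted p = 0.00755) and tp53inp1 by 1.04 (adjusted p = 0.0175). Among apoptosis genes, bcl2l1, a gene against cell death, rose by 0.54 (adjusted p = 0.0124). In the heat shock list hsp70l was at 2.95 (adjusted p = 0.0157), a call that ended when single arrays were left out (2 of the 16).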
